A study of Homo sapiens with 38 samples.

How the data were processed

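The deposited table gives linear probe set intensities from the authors for 38 arrays, 1.86 to 19876 where listed, and no raw scans were used here. How these values were summarised and scaled and which software and detection rule were used is not given in the sources used here. Of 2077650 cells 54.0% held no value (not listed), mostly for dim probe sets, and 12089 of 54675 probe sets were listed on no array. Every column was matched to a sample, with 0 left over. No 2 arrays were identical. Of the probe sets 41097 map to 1 gene, 1801 to several and 11777 to none, and 41043 single-gene symbols were brought up to date with a gene table of assembly GRCh38.p14. That assembly served for names and gene order only, and no positions are given.

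The comparisons, the filter, the test and all but 3 of the alternatives were fixed before the data were examined. What the plan did not foresee was the share of cells not listed. These were set to a floor, medians were taken over listed values, and the scaling was learnt on the probe sets listed everywhere. Values entered as log2 of intensity plus 16, so differences of dim probe sets are smaller than the raw ratio. Over the 15709 probe sets listed on all arrays the column medians ran from 7.77 to 7.92, more than the planned bound of 0.1, so a quantile map was learnt there and applied to all values. Cells not listed took the floor of 4.16. Probe sets had to exceed the median of the table (6.47, an intensity of 72.7) on at least 2 arrays. After 62 control probe sets were left out 15199 were tested: 13474 of them (88.7%) map to 1 gene, 8381 genes in all, 13922 were listed on all 38 arrays, and 1.03% of their cells were not listed.

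Counts and genes come from limma, with 12 arm means over all arrays and cell line within experiment (13 lines) as a random block. The correlation between arrays of a line was 0.126 and the residual degrees of freedom were 26. Moderated p values with a trend were adjusted by Benjamini-Hochberg over the probe sets tested, and an adjusted p below 0.05 counts as passing. Control against control, clone against clone and each line against each control used a fit of the 19 groups with 19 degrees of freedom. With 2 arrays per line and 1 or 2 lines per arm, p measures the spread among arrays and lines and not among separate knockdowns of one gene. The series text calls separate lines biological replicates. Whether the 2 arrays of a line are separate cultures or repeats of one RNA is not stated. If they are repeats, the Ago2, Ago3 and vector arms hold 1 sample each and p measures array spread there. The labels give 1 analysis day per experiment, and no knockdown contrast crosses experiments. The closing text compares like controls of 2 experiments, where the day differs too. Residual correlation of equal replicate numbers passed 0.1 in 1 of 6, 10 of 15 and 2 of 36 pairs of groups. In experiment 2 these were all 10 pairs without the shRNA control, 0.154 to 0.542, so numbers tie most arrays there. Replicate was not a block in the stated results or in the simulations and is given as an alternative.

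By the stated rule, the genes named for each knockdown are the 10 largest rises and the 10 largest falls, 1 probe set per gene, that pass for every knockdown line against every control line. The induction responses take 5 each way, and gene lists with a passing test up to 4 members. Genes of the comparisons with few passing probe sets, of the shRNA control comparison and of lists that did not pass were chosen after the values were seen. Those genes, and list members outside the rule, were not refitted with 1 array left out. Gene lists (29 measured, 9 comparisons, 261 tests) were tested with camera at a preset correlation of 0.01, on 1 probe set per gene, adjusted over all 261 tests. The estimated correlation also gave 35 calls, and fry, which asks a self-contained question, gave 57. Seed sites of microRNAs or hairpins in 3′ UTRs were not tested, as no transcript sequences were at hand. Small RNA and protein levels were not analysed here.

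In simulated data 200 of the 15199 probe sets were given changes of log2 0.5, 1 or 2. The spread drawn was that between arrays of one line, and all probe sets had the same line correlation of 0.126. The fit found 41.8%, 94.0% and 100% of them in the Ago1 comparison, 41.8%, 86.6% and 98.5% for Ago2, 23.9%, 80.6% and 100% for Dicer at 2 days, 13.4%, 55.2% and 97.0% for the 6-day response and 38.8%, 76.1% and 98.5% for the control lines of experiment 2. False calls were 4.85%, 4.43%, 4.23%, 1.79% and 18.4% of all calls, the last because 1 line stands on each side there and the drawn line effects count as differences. That last case had 32 false calls. Real lines of one kind differed at 1 (Ago1 clones) to 1274 (Dicer clones at 6 days) probe sets. The simulation may therefore understate false calls from line differences. R 4.3.3 with limma 3.58.1 and statmod 1.5.0 and Python 3.11.15 with matplotlib 3.10.9 were used, with a random seed of 1.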

Results

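The series asks which transcripts depend on the 4 human Argonaute proteins, which hold microRNAs in the silencing complex, and on Dicer, the nuclease that cuts microRNA precursors. RNA came from T-REx-293 cells, a HEK293 derivative that makes the tet repressor, and was read on 38 single-colour arrays in 19 groups of 2 replicates. Experiment 1 held the T-REx and shRNA control lines with Ago2 and Ago3 knockdown lines. Experiment 2 held the same 2 kinds of control with 2 clones each of Ago1 and Ago4 knockdown. Experiment 3 held an empty vector line and Dicer knockdown clones 2-2 and 2b2, each with no induction named, after 2 days and after 6 days of induction. The first are called before induction below, though whether those cells were untreated is not stated. Differences are log2 values of knockdown minus control with standard errors (SE), intensities are means ± SD over arrays, and n counts arrays, of which it is not stated whether the 2 of a line are separate cultures. Replicate arrays of a group had correlations of 0.953 to 0.994 over the probe sets. The replicate 1 arrays of the 4 Ago1 and Ago4 clones listed 19718 to 21135 probe sets, against 23516 to 25005 on the other arrays of experiment 2. The ratio of 3′ to 5′ ACTB signal, which is higher in shorter RNA, was 3.10 and 3.59 on the replicate 2 arrays of the Dicer clones with no induction named and at most 2.23 on the other arrays of experiment 3.

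The first comparison asks how far each hairpin lowered its own target. AGO1 fell by 2.68 in the Ago1 clones (SE 0.19, adjusted p = 9.71e-12, 15.9 ± 3.34 on 4 arrays against 205 ± 71.0 on 4), and a second AGO1 probe set fell by 2.48 (SE 0.17, adjusted p = 2.13e-12). AGO2, the only Argonaute of the 4 that cleaves target RNA in most settings, fell by 2.64 in the Ago2 line (SE 0.17, adjusted p = 1.25e-13, 29.8 ± 4.06 on 2 arrays against 266 ± 14.2 on 4). AGO3 was dim: it fell by 0.87 in the Ago3 line (SE 0.24, adjusted p = 0.0282), with an intensity of 4.42 on the 1 of 2 arrays that listed it against 20.1 ± 2.61 on 4 control arrays. Without Ago3 replicate 1 AGO3 differed by -0.97 (adjusted p = 0.106), without Ago3 replicate 2 by -0.78 (adjusted p = 0.281) and without T-REx replicate 2 by -0.83 (adjusted p = 0.0641). AGO4 in the 2 Ago4 clones together had a difference of -1.19 (SE 0.33, adjusted p = 0.536), made up of -2.24 in clone 1 and -0.14 in clone 2 (adjusted p = 0.879). DICER1 in the Dicer clones fell by 1.14 with no induction named (SE 0.18, adjusted p = 0.000620), by 2.54 at 2 days (SE 0.18, adjusted p = 9.36e-12) and by 2.56 at 6 days (SE 0.18, adjusted p = 1.05e-11), with 4 against 2 arrays each time. Without the first empty vector array the difference with no induction named was -0.96 (adjusted p = 0.0509). Its second probe set fell by 1.46 before induction (adjusted p = 0.00913, and 0.127 or 0.0513 without vector replicate 1 or 2), and a further one had -0.86 (adjusted p = 0.105). AGO1 rose in the Ago2 line by 1.17 (SE 0.24, adjusted p = 0.000830, 398 against 170) and by 0.74 on its second probe set (SE 0.21, adjusted p = 0.0144). AGO4 there had a difference of -1.05 (adjusted p = 0.0923).

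**Figure D1:**
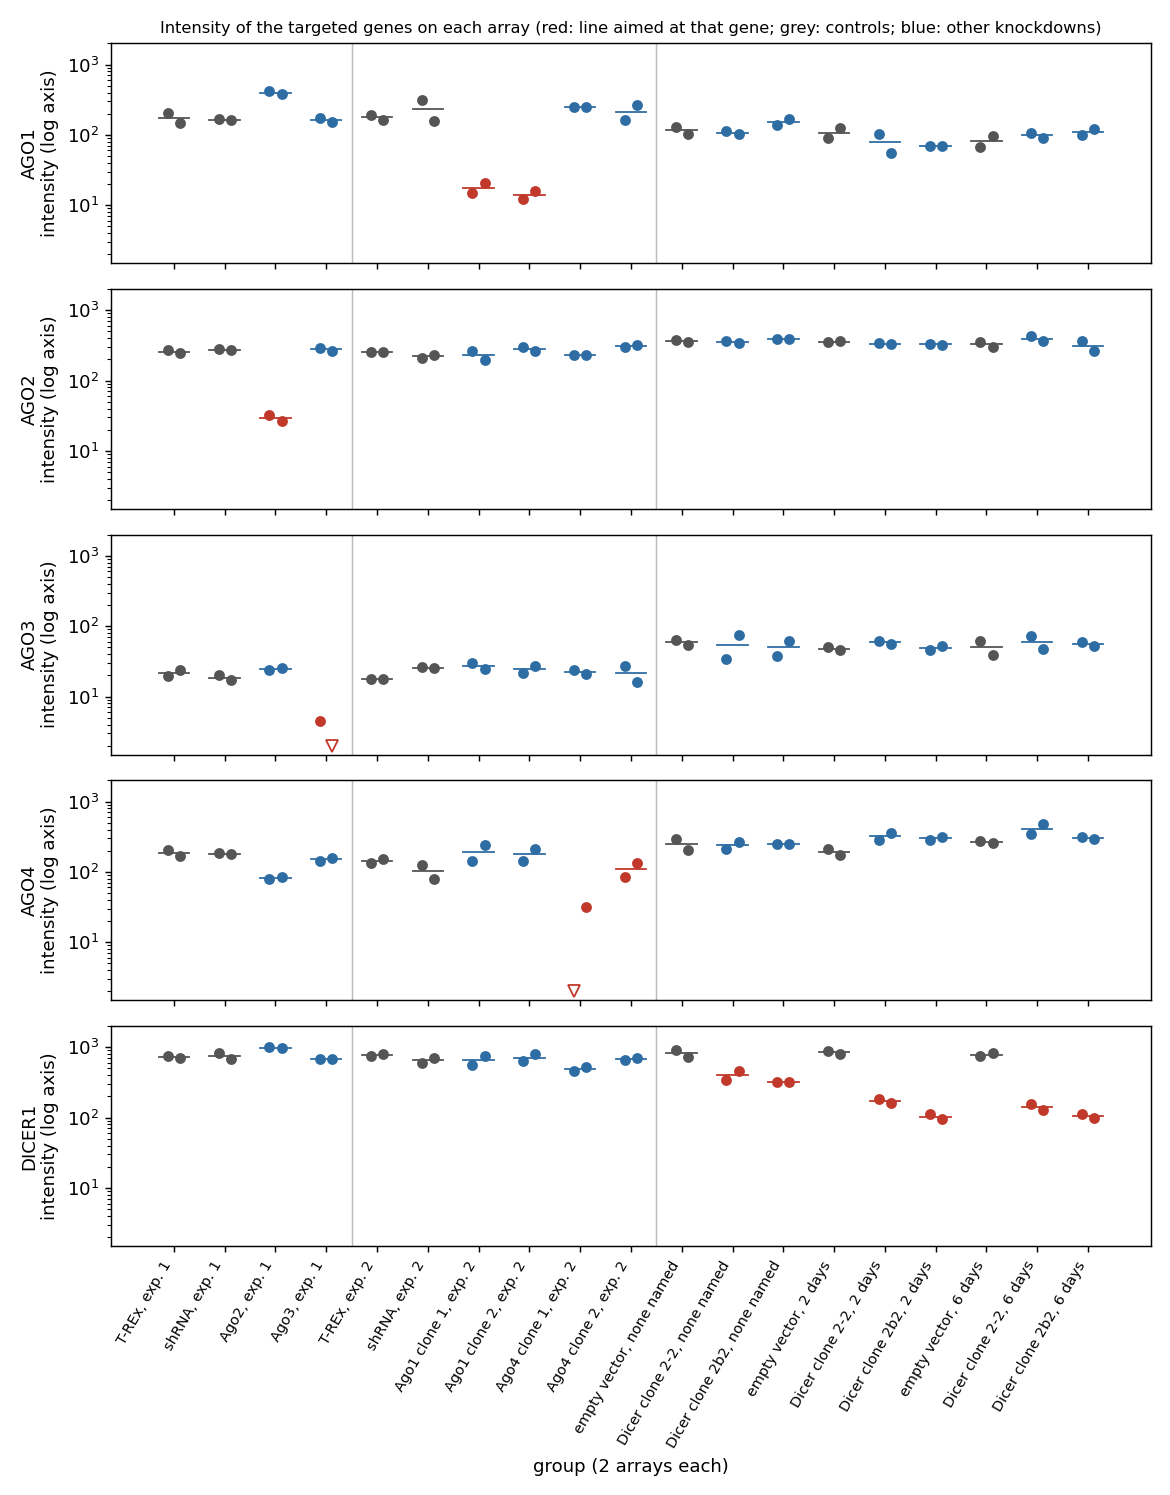
Intensity of AGO1, AGO2, AGO3, AGO4 and DICER1 on each of the 38 arrays, by group. Open triangles mark arrays on which the probe set was not listed.

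With Ago1 lowered (4 knockdown and 4 control arrays), RANBP17, a transport receptor of the importin family, had the largest fitted rise, 3.60 (SE 0.16, adjusted p = 1.61e-17, 210 ± 42.5 against 4.39 on 1 of 4 control arrays). The other control arrays took the floor, so the size, SE and rank of this rise depend on it. HMOX1, which degrades haem under oxidative stress, rose by 1.67 (SE 0.27, adjusted p = 3.83e-05, 748 ± 100 against 229 ± 42.4). SLC7A11, the cystine importer that feeds glutathione synthesis, rose by 1.36 (SE 0.20, adjusted p = 9.37e-06, 266 ± 55.4 against 100 ± 30.1). APOBEC3B, a DNA cytidine deaminase, fell by 2.49 (SE 0.28, adjusted p = 9.84e-08, 73.7 ± 57.9 against 438 ± 110). GNG10, a G protein gamma subunit, fell by 1.95 (SE 0.15, adjusted p = 6.34e-11, 375 ± 128 against 1511 ± 314). The other large rises were PLBD1, a phospholipase B-like protein, at 2.62 (SE 0.31), NFKBIB, an inhibitor of NF-kappaB, at 2.20 (SE 0.36, listed on 2 of 4 control arrays), and IFI16 at 1.69 (SE 0.58, 3 of 4). The Ras exchange factor SOS1 (1.46, SE 0.23), the integrin ITGA8 (1.42, SE 0.25), MOK (1.41, SE 0.19) and TCAIM (1.38, SE 0.18) rose too. NME5 was listed on none of the 4 Ago1 arrays and at 138 ± 28.0 on all control arrays. Falls also took in the motor protein KIF5C at -2.88 (SE 0.32, listed on 1 of 4 Ago1 arrays), HOXD4 at -2.32 (SE 0.19, 2 of 4), and SPTSSA of sphingolipid synthesis at -2.26 (SE 0.21). IGFBPL1 (-1.97, SE 0.27, 3 of 4), the corepressor RUNX1T1 (-1.86, SE 0.30) and the RNA-binding protein TIA1 (-1.79, SE 0.25, 3 of 4) fell as well. IFI16 lost its call without any of 5 arrays, with an adjusted p of up to 0.126 without shRNA control replicate 2.

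In all, 975 probe sets rose and 1353 fell in the Ago1 clones (2328 of 15199, 729 and 991 genes), and 612 held for each clone against each control line. Left as deposited without rescaling, the values gave 762 that rose and 1672 that fell, with a median difference of -0.05. Without the 4 short-listing replicate 1 arrays of the Ago1 and Ago4 clones 1359 probe sets passed. Of 31 measured genes of the amino acid and ER stress response 9 rose, 0 fell and 22 did not pass (adjusted over the list alone, 10 rose and 1 fell; median 0.25, adjusted p = 0.000407). The secreted glycoprotein STC2 rose by 1.23 (SE 0.16) and the glutathione-degrading enzyme CHAC1 by 1.22 (SE 0.23). Among 9 histone genes 0 rose and 3 fell (adjusted over the list alone, 5 fell; median -0.37, adjusted p = 0.0377), among them H2BC12 at -0.54 (SE 0.11). The cell cycle list had 5 of 30 that rose and 1 that fell (adjusted over the list alone, 8 and 1; median 0.16, adjusted p = 0.0427), with CENPF at 0.53, PLK1 at 0.48 and NUSAP1 at -0.31. Of 5 metallothionein-list genes 0 rose and 3 fell, also adjusted over the list alone (median -0.58, adjusted p = 0.0427, and adjusted p = 0.117 with an estimated correlation). MT1H fell by 1.25, MT1X by 1.13 (SE 0.23) and MT2A by 0.58 (SE 0.11), all metal-binding proteins. Leaving out 1 array took the histone list to an adjusted p of 0.120 and the cell cycle list to 0.121 (both without shRNA control replicate 1) and the metallothioneins to 0.0842 (shRNA control replicate 2). Against the T-REx control alone the histone list had an adjusted p of 0.386, the metallothioneins 0.196 and the cell cycle list 0.109. The stress list still passed there. CENPF and PLK1 had an adjusted p of 0.0822 and 0.0801 without shRNA control replicate 1, and MT1H of 0.253 without Ago1 clone 1 replicate 1.

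In the Ago2 line (2 arrays against 4), LRATD2, a little-studied LRAT-domain protein, had the largest fitted fall among the genes named by the rule, -4.34 (SE 0.22, adjusted p = 6.13e-16, 29.0 ± 1.86 against 891 ± 58.7). Genes listed on neither Ago2 array took the floor, so the size of their falls depends on it and the order is not settled. IPO7, an importin that carries ribosomal proteins and histones into the nucleus, fell by 3.18 (SE 0.12, adjusted p = 3.95e-19, 48.9 ± 0.161 against 567 ± 28.9). TP53I3, a quinone oxidoreductase induced by p53, had the largest rise of a gene listed in both arms, 2.60 (SE 0.38, adjusted p = 9.07e-06, 363 ± 29.5 against 47.2 ± 3.34). MT1F, a metallothionein, rose by 1.97 (SE 0.33, adjusted p = 7.45e-05, 236 ± 61.6 against 49.2 ± 16.8), and QPRT, an enzyme of NAD synthesis, by 1.87 (SE 0.31, adjusted p = 7.16e-05, 287 ± 24.3 against 68.5 ± 14.1). CARD6 (87.1 ± 16.1) and ATG13 (116) were listed in the Ago2 line and on none of the 4 control arrays. Further rises were ITGA8 at 1.92 (SE 0.31), the glutathione transferase GSTT2 at 1.91 (SE 0.26), SYT11 at 1.78 (SE 0.28), the secreted glutathione peroxidase GPX3 at 1.76 (SE 0.29) and LRRC17 at 1.70 (SE 0.30). SOX11, PUDP, CALB1 and PSMD5 were listed on neither Ago2 array, against 243 ± 126, 202 ± 11.2, 147 ± 65.6 and 92 ± 9.99 in the controls. RUNX1T1 fell by 3.10 (SE 0.36), the surface protein CD99 by 3.08 (SE 0.54) and ANXA1 by 2.59 (SE 0.73). Without Ago2 replicate 1 or replicate 2 the adjusted p was 0.0977 or 0.145 for ATG13, 0.0627 or 0.0601 for SOX11, 0.107 or 0.103 for PUDP and 0.115 or 0.0790 for ANXA1.

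Altogether 728 probe sets rose and 1128 fell in the Ago2 line (1856, 551 and 817 genes), 1434 of them against each control line, and 809 passed without Ago2 replicate 1 and 880 without replicate 2. Of 21 p53 targets 7 rose, 0 fell and 14 did not pass (adjusted over the list alone, 10 rose; median 0.31, adjusted p = 0.00444). Beside TP53I3, the cytokine GDF15 rose by 1.65 (SE 0.40), TP53INP1 by 1.16 (SE 0.27) and ZMAT3 by 1.02. CDKN1A, the p21 cell cycle inhibitor, rose by 1.22 (adjusted p = 0.00155). It is not on the p53 list but on a list of microRNA targets tested below, and TP53INP1 is on both. Among 8 epithelial genes 0 rose and 3 fell, also adjusted over the list alone (median -0.63, adjusted p = 0.0180): KRT19 fell by 0.96, KRT18 by 0.75 (SE 0.12) and EPCAM by 0.48. Without Ago2 replicate 1 GDF15 had an adjusted p of 0.0762, and without replicate 1 or 2 KRT19 had 0.120 or 0.0705 and ZMAT3 0.0828 or 0.114.

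In the Ago3 line (2 arrays against 4), LRATD1 was listed at 478 ± 70.7 and on none of the control arrays. BEX5, of a family of small adaptor proteins, rose by 3.96 (SE 0.57, adjusted p = 2.33e-05, 417 ± 98.9 against 11.8 ± 1.21). EEF1A2, a translation elongation factor of neurons and muscle, rose by 2.13 (SE 0.19, adjusted p = 1.44e-09, 2867 ± 203 against 658 ± 160). EGR1, an immediate early transcription factor, rose by 2.35 (SE 0.39, adjusted p = 0.000160, 271 ± 36.4 against 42.7 ± 9.62). IFIH1, a sensor of double-stranded RNA, rose by 2.26 (SE 0.36, adjusted p = 0.000104, 202 ± 71.9 against 30.3 ± 8.22). GPC3, a cell surface proteoglycan, fell by 2.07 (SE 0.23, adjusted p = 1.56e-07, 53 ± 2.23 against 281 ± 24.8). The monocarboxylate transporter SLC16A7 (2.50, SE 0.32, listed on 3 of 4 control arrays), NAP1L2 (2.06, SE 0.26), TMEM47 (1.99, SE 0.53) and the mitochondrial ND6 (1.91, SE 0.38) also rose, and CARD6 was listed at 55.4 and on no control array. CALB1, PYCR1 of proline synthesis, the motor protein KIF1A, C2orf68 and SOX11 were listed on neither Ago3 array, against 147, 136 ± 24.4, 114 ± 33.5, 53.8 and 243 in the controls. Falls were also found for IFI16 (-3.41, SE 1.02, listed on 1 of 2 Ago3 arrays), FN1 (-1.87, SE 0.51), PAAF1 (-1.82, SE 0.16) and EFEMP1 (-1.75, SE 0.31). Leaving out Ago3 replicate 2 took the adjusted p to 0.389 for IFI16, 0.207 for FN1, 0.183 for TMEM47 and 0.138 for SOX11, and leaving out replicate 1 to 0.141, 0.141, 0.129 and 0.122. IFI16 also lost its call without any 1 control array (at most 0.0837), FN1 without T-REx replicate 1 (0.0647) and TMEM47 without shRNA control replicate 2 (0.0580).

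In the Ago3 line 418 probe sets rose and 275 fell (693, 315 and 208 genes), 541 against each control line, with 239 left without Ago3 replicate 1 and 227 without replicate 2. The amino acid and ER stress response had 0 of 31 that rose and 11 that fell (adjusted over the list alone, 2 and 17; median -0.37, adjusted p = 3.99e-11). SLC7A11, which feeds glutathione synthesis, fell by 1.35 (SE 0.19), CHAC1 by 1.13, asparagine synthetase ASNS by 1.03 (SE 0.10) and STC2 by 0.87. Cholesterol synthesis had 0 of 18 that rose and 1 that fell (adjusted over the list alone, 3 fell; median -0.32, adjusted p = 0.000668), the reductase DHCR7 at -1.42 (SE 0.18). Of 6 Wnt targets 2 fell (adjusted over the list alone, 4; median -0.50, adjusted p = 0.00216): the R-spondin receptor LGR5 at -1.46 and the G1 cyclin CCND1 at -1.12. Of 9 interferon-stimulated genes 3 rose and 0 fell (adjusted over the list alone, 4 and 1; median 0.38, adjusted p = 0.00221): IFIH1, PARP9 at 1.38 (SE 0.19) and IFIT1 at 1.14. Extracellular matrix genes had 0 of 26 that rose and 3 that fell (adjusted over the list alone, 1 and 7; median -0.20, adjusted p = 0.00918, and adjusted p = 0.239 with an estimated correlation), with TIMP2 at -0.86 and COL6A1 at -0.77 (SE 0.16). Of 15 heat shock genes the cochaperones CHORDC1 (0.65) and DNAJA1 (0.32) rose, also adjusted over the list alone (median 0.16, adjusted p = 0.0197). Of 15 immediate early genes 4 rose (adjusted over the list alone, 5; median 0.16, adjusted p = 0.0283), among them EGR1 and the phosphatase DUSP1 at 0.59. Without Ago3 replicate 2 the heat shock list had an adjusted p of 0.0512 and the immediate early list 0.105, and of their members CHORDC1 had 0.448, DUSP1 0.0542, IFIT1 0.240 and CCND1 0.0613. CHAC1 had an adjusted p of 0.107 or 0.115 without Ago3 replicate 1 or 2, and LGR5 and TIMP2 had 0.0638 and 0.234 without replicate 1. CHORDC1 also lost its call without Ago3 replicate 1 (0.0727) or either T-REx array (at most 0.0921), and IFIT1 without Ago3 replicate 1 (0.0790).

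In the Ago4 clones (4 arrays against 4), 1 probe set rose and 3 fell by limma, with 1214 at an unadjusted p below 0.05. AGO4 itself was lower in clone 1 alone (-2.24, adjusted p = 1.91e-06) and not in clone 2 (-0.14, adjusted p = 0.879), so 2 of the 4 arrays show no knockdown. PLBD1 rose by 1.78 (SE 0.31, adjusted p = 0.0271). The growth hormone receptor GHR fell by 1.41 (SE 0.26), CRISPLD1 by 1.22 (SE 0.23) and PRKG1, a cyclic GMP-dependent kinase, by 1.41 (SE 0.27, 18.2 ± 2.06 on 2 of 4 arrays against 51.9 ± 5.39), each with an adjusted p of 0.0360. Only PRKG1 held for each clone against each control line, and it lost its call without any of 6 of the 8 arrays (at most 0.230, without clone 1 replicate 1). The count was 0 without clone 1 replicate 1 or either shRNA control array, 1 without T-REx replicate 2, 2 without clone 2 replicate 1, 7 without clone 1 replicate 2 and 15 without clone 2 replicate 2. As deposited, the values gave 1 that rose and 1 that fell, and 0 passed without the 4 short-listing arrays. None of the 29 gene lists passed at the preset correlation, the lowest adjusted p being 0.0516 for the p53 targets (median 0.12), which had 0.0499 with an estimated one. The 2 clones differed from each other at 193 probe sets.

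**Figure D2:**
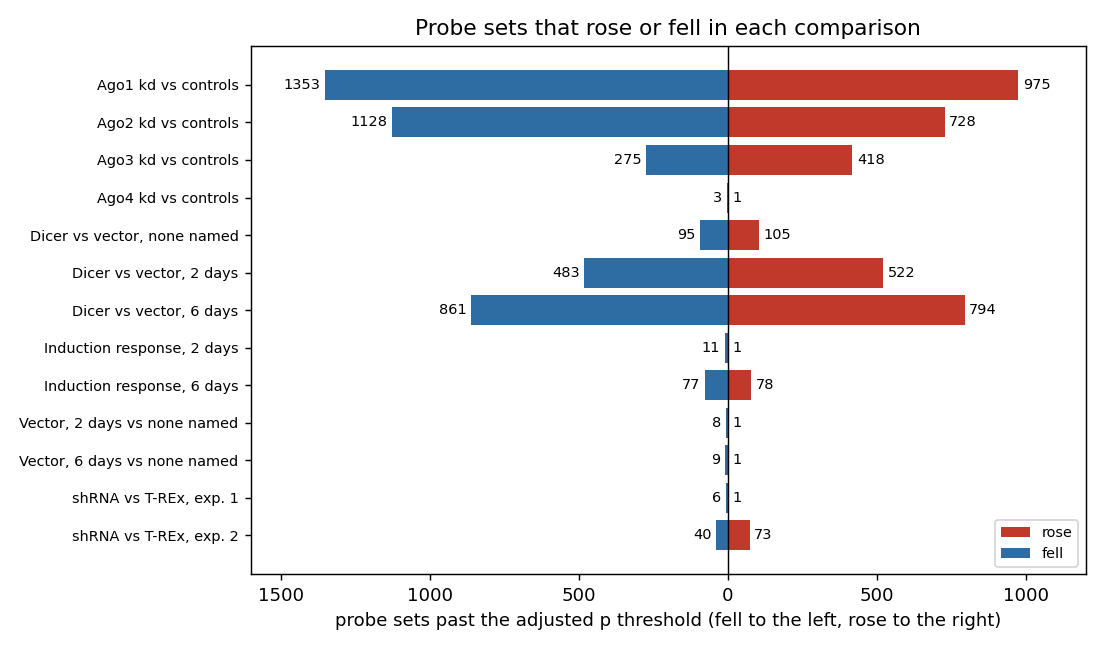
Numbers of probe sets that rose and fell in each of the 13 comparisons, of 15199 tested.

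The Dicer comparison with no induction named (4 arrays against 2) asks what differs before the hairpin is named as induced. LRATD2 rose by 4.68 (SE 0.22, adjusted p = 1.86e-16, 1186 ± 225 against 35 ± 23.5). ALOX5, the lipoxygenase of leukotriene synthesis, rose by 2.02 (SE 0.27, adjusted p = 5.86e-05, 142 ± 25.8 against 24.8 ± 13.5), and HOXD13, a limb patterning factor, by 1.67 (SE 0.20, adjusted p = 1.17e-05, 376 ± 86.6 against 110 ± 25.5). CGA, the shared subunit of glycoprotein hormones, fell by 2.81 (SE 0.36, adjusted p = 2.13e-05, 26.5 ± 11.9 on 3 of 4 arrays against 230 ± 36.1). LGR5 fell by 2.13 (SE 0.32, adjusted p = 0.000275, 31.2 ± 20.6 against 193 ± 23.0) and CYP4X1, a cytochrome P450, by 1.43 (SE 0.24, adjusted p = 0.00117). Other rises were TIGD1 at 1.07 (SE 0.14), BTNL9 at 1.18, CCND1 at 1.15, HES6 at 1.10 and CFLAR at 1.09, and ZC3H7B (85.3) and PNMA8A (59.2) were listed in the clones and on neither vector array. Falls also took in STS at -2.45 (listed on 2 of 4 arrays), ZNF85 at -1.61 (1 of 4), ZFAS1 at -1.28, CCDC50 at -1.22, KLHL7 at -1.20 and TSPAN31 at -1.18. Without empty vector replicate 1 or 2 the adjusted p was 0.0801 or 0.1004 for PNMA8A, 0.0602 or 0.1004 for CCND1, 0.0602 or 0.0910 for STS, 0.158 or 0.207 for ZC3H7B, 0.0602 or 0.289 for HES6 and 0.0602 or 0.250 for CFLAR. It was 0.0678 or 0.0762 for CCDC50, 0.0817 or 0.0685 for KLHL7 and 0.0597 or 0.242 for TSPAN31. For BTNL9 it was 0.0643 and for ZFAS1 0.195 without replicate 1, and for ZNF85 0.0925 without replicate 2.

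With no induction named 105 probe sets rose and 95 fell (200, 88 and 74 genes), 143 in both clones, and as deposited 71 rose and 122 fell. Leaving out empty vector replicate 1 or 2 gave 41 or 39, Dicer 2-2 replicate 1 gave 434, 2b2 replicate 2 gave 123, and leaving out the 2 arrays of high ACTB ratio gave 268. No DNA replication gene of 36 passed, nor adjusted over the list alone, while the list as a whole was lower (median -0.13, adjusted p = 0.00440). Of 23 hypoxia and glycolysis genes 1 fell (adjusted over the list alone, 2; median -0.12, adjusted p = 0.0148), lactate dehydrogenase LDHA at -0.23. Of 31 amino acid and ER stress genes 2 fell, also adjusted over the list alone (median -0.11, adjusted p = 0.0239), STC2 at -0.90 and ASNS at -0.39 (SE 0.10). With clone 2-2 alone the hypoxia list had an adjusted p of 0.892 and the DNA replication list 0.0622. With clone 2b2 alone the stress list had 0.190. Leaving out 1 array took the hypoxia list to an adjusted p of 0.126 (a 2b2 array) and the stress list to 0.0546 (a 2-2 array), and STC2 had 0.0532 or 0.250 without empty vector replicate 1 or 2.

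After 2 days of induction (4 Dicer arrays against 2), ATP6V0E2, a subunit of the proton pump of lysosomes, fell by 2.72 (SE 0.18, adjusted p = 7.16e-13, 43.8 ± 9.69 against 370 ± 34.6), more than DICER1. UNG, which removes uracil from DNA, fell by 1.60 (SE 0.18, adjusted p = 3.32e-07, 299 ± 101 against 889 ± 92.3). LARS2, the mitochondrial leucyl-tRNA synthetase, fell by 1.66 (SE 0.19, adjusted p = 1.14e-06, 110 ± 14.6 against 375 ± 19.9). LRATD2 rose by 5.01 (SE 0.22), ALOX5 by 1.94 (SE 0.27, adjusted p = 3.09e-05), HOXD13 by 1.90 (SE 0.20), the collagen COL14A1 by 1.87 (SE 0.34) and the splicing factor RBM24 by 1.66 (SE 0.30). The chemokine-like factor CKLF (165 ± 27.0) and PNMA8A (105) were listed in the clones and on neither vector array. A CKLF probe set fell by 3.17 in the vector line itself between no induction named and 2 days (adjusted p = 5.79e-12 by limma). CCND2 fell by 1.66 (SE 0.30), MTDH by 1.58 (SE 0.24), the cholesterol-esterifying SOAT1 by 1.52 (SE 0.22), NFATC3 by 1.48 (SE 0.22), CYP4X1 by 1.42 (SE 0.24) and STS by 2.13 (SE 0.49, 2 of 4 arrays). NKRF (273 against 291 on 1 of 2 vector arrays), MNX1 (216 against 197 on 1 of 2) and ZCCHC12 (852 against 242) also passed as higher. Without empty vector replicate 2 NKRF differed by -0.13 and ZCCHC12 by 1.48 (adjusted p = 0.0826), and without replicate 1 MNX1 differed by 0.11 (adjusted p = 0.863) and STS by -1.91 (adjusted p = 0.0809).

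At 2 days 522 probe sets rose and 483 fell (1005, 427 and 342 genes), 615 in both clones, with 393 or 310 left without empty vector replicate 1 or 2. DNA replication genes had 0 of 36 that rose and 3 that fell (adjusted over the list alone, 6; median -0.17, adjusted p = 0.00216), among them the helicase subunits MCM3 at -0.38 (SE 0.09) and MCM2 at -0.37. The amino acid and ER stress response had 5 of 31 that fell (adjusted over the list alone, 1 rose and 7 fell; median -0.18, adjusted p = 0.00412), with STC2 at -1.05 (SE 0.20) and ASNS at -0.69 (SE 0.10). Of 26 extracellular matrix genes 4 rose, also adjusted over the list alone (median 0.23, adjusted p = 0.0198, and adjusted p = 0.299 with an estimated correlation), among them fibrillin FBN1 at 1.44 (SE 0.24) and COL6A1 at 0.82 (SE 0.16). Of 21 p53 targets 2 rose and 1 fell (adjusted over the list alone, 5 and 1; median 0.33, adjusted p = 0.0369): the death receptor FAS rose by 0.91 (SE 0.15) and TRIAP1 fell by 0.78 (SE 0.14). The 1 of 5 metallothionein-list genes that rose, also adjusted over the list alone, was SLC30A1 at 0.94 (SE 0.15), a zinc exporter and not a metallothionein (median 0.63, adjusted p = 0.0377, and adjusted p = 0.106 with an estimated correlation). With clone 2b2 alone the adjusted p was 0.543 for the matrix list and 0.348 for the metallothionein list. It was 0.104 for the p53 targets and 0.0550 for the stress list. The DNA replication list passed with either clone alone. Leaving out 1 empty vector array took the p53 list to an adjusted p of 0.117 and the metallothionein list to 0.183, and leaving out 1 Dicer 2-2 array took the matrix list to 0.0532.

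After 6 days (4 arrays against 2), ALOX5 rose by 2.52 (SE 0.27, adjusted p = 2.62e-07, 399 ± 70.9 against 55.8 ± 3.08). ZCCHC12, a zinc knuckle protein of neurons, rose by 2.07 (SE 0.36, adjusted p = 0.000248, 1210 ± 204 against 277 ± 51.1). ATP6V0E2 fell by 2.58 (SE 0.18, adjusted p = 4.54e-12, 37.1 ± 8.82 against 292 ± 4.46), LARS2 by 1.81 (SE 0.19, adjusted p = 2.01e-07, 87.3 ± 31.3 against 323 ± 8.96) and SOAT1 by 1.78 (SE 0.22, adjusted p = 1.77e-06). NUDT1, which clears oxidised nucleotides, fell by 1.47 (SE 0.23), and RRP36, a ribosomal RNA processing factor, by 1.46 (SE 0.17). LRATD2 (4.57, SE 0.22), ENPP5 (2.22, SE 0.37), SMIM10L2A (2.03, SE 0.28) and COL14A1 (1.99, SE 0.34) also rose, and PNMA8A (110) and the mitochondrial polymerase POLG (63.9) were listed on neither vector array. A POLG probe set fell by 2.34 in the vector line itself between no induction named and 6 days (adjusted p = 0.0245 by limma). Falls further took in STS (-1.92, SE 0.49, 2 of 4 arrays), LTAP1 (-1.83, SE 0.22), CYP4X1 (-1.63, SE 0.24) and ZNF232-AS1 (-1.54, SE 0.22). NACA4P (1020 against 898 on 1 of 2 vector arrays) and ZNF652 (408 against 166 ± 209) passed as higher. NACA4P differed by 0.16 (adjusted p = 0.593) without empty vector replicate 2 and ZNF652 by 0.34 (adjusted p = 0.455) without replicate 1. STS had an adjusted p of 0.0776 without replicate 1.

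At 6 days 794 probe sets rose and 861 fell (1655, 614 and 630 genes), 1079 in both clones, with 556 or 960 left without empty vector replicate 1 or 2. Of 21 p53 targets 10 rose and 1 fell (adjusted over the list alone, 11 and 1; median 0.43, adjusted p = 9.21e-05), with FAS at 1.11 (SE 0.15), TP53I3 at 1.40, ZMAT3 at 1.09 and the reductase subunit RRM2B at 0.97. CDKN1A rose by 1.04 (SE 0.26, adjusted p = 0.00835). The amino acid and ER stress response had 2 of 31 that rose and 11 that fell (adjusted over the list alone, 2 and 13; median -0.27, adjusted p = 5.37e-05). STC2 fell by 1.27 (SE 0.20), SLC7A11 by 1.27 (SE 0.19) and ASNS by 1.12 (SE 0.10). DNA replication had 0 of 36 that rose and 9 that fell (adjusted over the list alone, 12; median -0.20, adjusted p = 0.000407), with the origin-firing factor CDC45 at -0.66 (SE 0.15), POLA1 at -0.62 and UHRF1 at -0.47. Of 13 TGF-beta targets 4 rose (adjusted over the list alone, 6; median 0.56, adjusted p = 0.000785), among them the matricellular protein CCN2 at 1.89 (SE 0.36) and the helix-loop-helix inhibitor ID2 at 0.80 (SE 0.15). Of 9 histone genes 5 rose, also adjusted over the list alone (median 0.98, adjusted p = 0.00221), with H4C8 at 1.56, H2BC5 at 1.20 (SE 0.22) and H2BC12 at 1.18 (SE 0.14). Extracellular matrix genes had 5 of 26 that rose (adjusted over the list alone, 6; median 0.24, adjusted p = 0.00689, and adjusted p = 0.220 with an estimated correlation), with FBN1 at 1.35 (SE 0.24) and COL6A1 at 1.10 (SE 0.16). With clone 2b2 alone this list had an adjusted p of 0.452, while the other lists named here passed with either clone alone. Leaving out empty vector replicate 2 gave an adjusted p of 0.131 for TP53I3 and 0.0613 for H4C8, replicate 1 gave 0.110 for CDC45, 0.109 for POLA1 and 0.156 for RRM2B. Without empty vector replicate 2 ZMAT3 had an adjusted p of 0.142 and the matrix list of 0.0574.

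The induction responses compare the change within the Dicer clones with that within the empty vector line, which removes fixed differences between lines (6 groups, 12 arrays at each time). At 2 days 1 probe set rose and 11 fell relative to the vector (12). ATP6V0E2 fell by 1.76 (SE 0.22, adjusted p = 2.49e-05, 43.8 against 180 in the Dicer clones before), GTPBP4, a ribosome assembly GTPase, by 1.17 (SE 0.15, adjusted p = 2.49e-05) and DICER1 by 1.40 (SE 0.23, adjusted p = 0.00111) on 1 of 3 probe sets. The other 2 did not pass (-0.90, adjusted p = 0.516, and -1.03, adjusted p = 0.344). GATAD2A of the NuRD complex fell by 1.65 (SE 0.25, adjusted p = 0.000490), the surface protein EMB by 1.21 (SE 0.19, adjusted p = 0.000696), and the snRNP protein SNRPB by 0.91 and 0.84 on 2 probe sets. TMEM245 (-0.85), TOMM5 (-0.51 and -0.46) and LARS2 (-1.19) made up the rest, and CKLF, the 1 higher value, was not listed on the vector arrays at 2 days while the Dicer clones held 165 against 128. The count was 7 without the second vector array of no induction, 26 without Dicer 2-2 replicate 1 of no induction, 21 without vector replicate 2 at 2 days and 30 without Dicer 2-2 replicate 1 at 2 days. It was 73 without the 2 arrays of high ACTB ratio, which enter this response, 55 with array weights and 165 with no filter. DICER1 had an adjusted p of 0.0686 and GATAD2A of 0.0523 without the second vector array of no induction. Relative to the vector, in which hypoxia genes such as HK2, PGK1 and BNIP3 fell at 2 days, the hypoxia list was higher with 0 of 23 passing (adjusted over the list alone, 3 rose; median 0.28, adjusted p = 0.000407). In the clones against the vector at 2 days it did not pass (median 0.05, adjusted p = 0.539). With clone 2-2 alone the 2-day response of the hypoxia list had an adjusted p of 0.154. Also higher relative to the vector were the metallothionein list with 0 of 5 (adjusted over the list alone, 1 rose; median 0.63, adjusted p = 0.00689) and the p53 targets with 0 of 21, also adjusted over the list alone (median 0.18, adjusted p = 0.0240). Leaving out 1 vector array of 2 days took the metallothioneins to an adjusted p of 0.0833 and the p53 targets to 0.112.

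At 6 days 78 probe sets rose and 77 fell relative to the vector (155, 69 and 65 genes), 41 in both clones. CGA rose by 3.18 (SE 0.45, adjusted p = 0.000103), having stood at 26.5 on 3 of 4 Dicer arrays before induction. The smooth muscle actin ACTA2 rose by 1.80 (SE 0.30, adjusted p = 0.00159, 968 ± 170 against 297 ± 31.7 in the clones before). The histone H2BC12L rose by 1.73 (SE 0.25, adjusted p = 0.000105), the germline cyclin CCNA1 by 1.94 (SE 0.34, adjusted p = 0.00208) and ENPP5 by 2.28 (SE 0.46). ATP6V0E2 fell by 1.62 (SE 0.22, adjusted p = 9.09e-05), GATAD2A by 1.58 (SE 0.25), ECSIT by 1.47 (SE 0.25), LTAP1 by 1.46 (SE 0.28) and DICER1 by 1.42 (SE 0.23, adjusted p = 0.000728), its other 2 probe sets having -1.04 (adjusted p = 0.178) and -1.08 (adjusted p = 0.106). Of 21 p53 targets 1 rose, FAS at 0.72 (adjusted over the list alone, 8; median 0.49, adjusted p = 5.37e-05). Of 9 histone genes H2BC12 rose by 1.33 (SE 0.17) and H2BC5 by 1.12 (adjusted over the list alone, 4; median 0.84, adjusted p = 0.000338). Of 13 TGF-beta targets CCN2 rose by 1.74 and ID2 by 0.73, also 2 adjusted over the list alone (median 0.34, adjusted p = 0.00689). The amino acid and ER stress list had 1 of 31 that fell, ASNS at -0.72 (SE 0.12; adjusted over the list alone, 2 rose and 7 fell; median -0.23, adjusted p = 0.0198). Of 9 interferon-stimulated genes PARP9 rose by 1.16 (adjusted over the list alone, 2; median 0.40, adjusted p = 0.0297). With clone 2b2 alone the stress and interferon lists each had an adjusted p of 0.190. The histone list had 0.0852 with clone 2-2 alone, while the p53 targets passed with either clone. The count was 59 or 33 without vector replicate 1 or 2 of no induction, 37 without vector replicate 1 at 6 days, 319 without Dicer 2-2 replicate 1, and 233 or 94 without 2b2 replicate 1 or 2 of no induction. Without vector replicate 1 at 6 days ENPP5 had an adjusted p of 0.148, CCN2 of 0.236, PARP9 of 0.0930 and the interferon list of 0.0791. Without vector replicate 2 of no induction LTAP1 had 0.0945, ECSIT 0.0539 and H2BC5 0.191, and without vector replicate 2 at 6 days ID2 had 0.180. CCN2, ID2 and H2BC5 each lost their call without any of 8 or 9 of the 12 arrays.

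**Figure D3:**
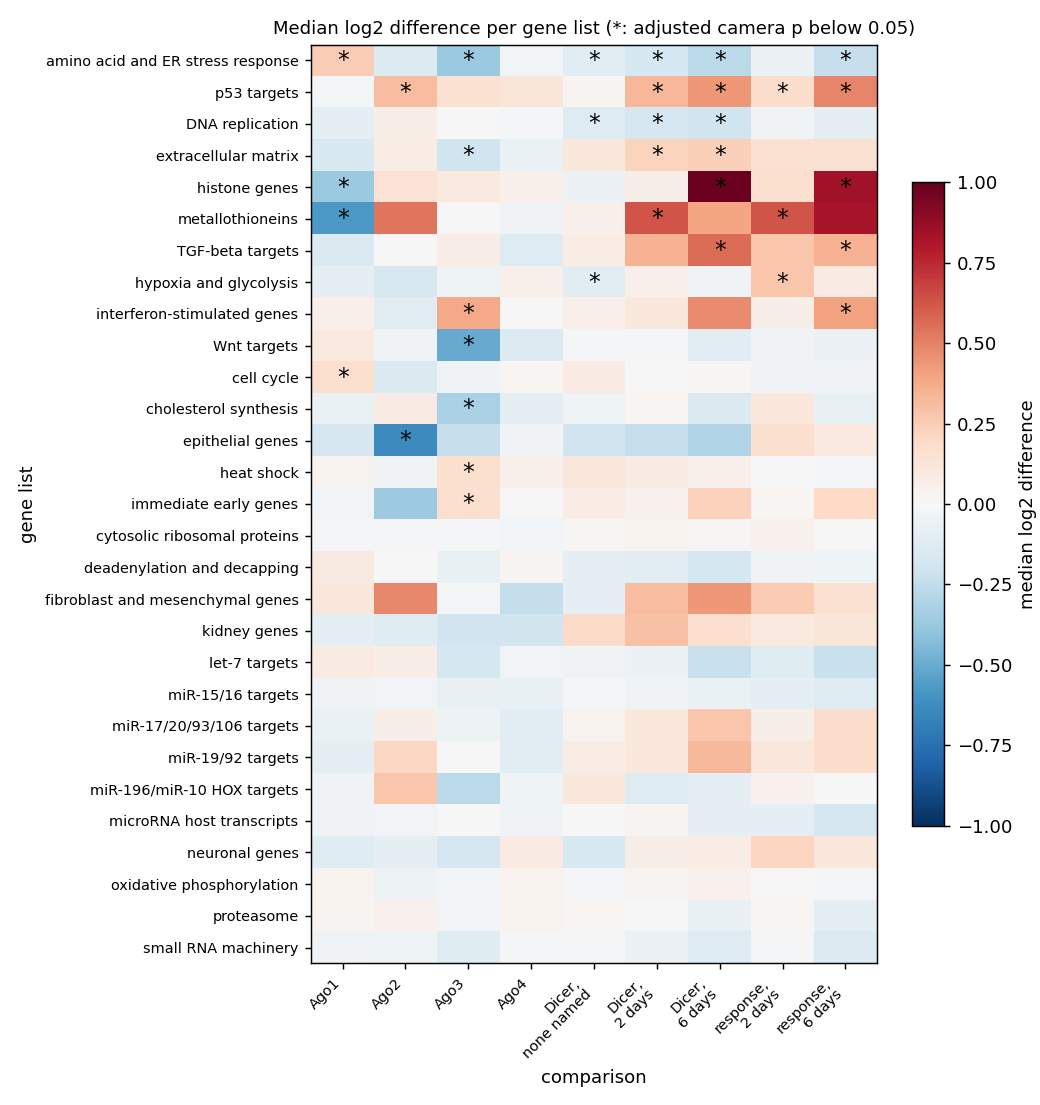
Median log2 difference of the measured members of each gene list in 9 comparisons. Stars mark an adjusted camera p below 0.05.

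In the empty vector line (2 arrays against 2) induction moved few genes by limma. At 2 days 1 rose and 8 fell, with 836 at an unadjusted p below 0.05. The collagen-modifying enzymes PLOD2 (-1.12, SE 0.16, adjusted p = 0.000319) and P4HA1 (-0.80), the glycolytic HK2 (-0.91, SE 0.13) and PGK1 (-0.38, SE 0.06), the mitophagy receptor BNIP3 (-0.93, SE 0.15), HILPDA (-1.29) and BTBD7 (-1.25) fell. WDR35 rose by 1.23, and CKLF was no longer listed. At 6 days 1 rose and 9 fell, with 1412 at an unadjusted p below 0.05. BNIP3 (-0.99, adjusted p = 0.000956), HK2 (-0.83), PGK1 (-0.35), PLOD2 (-0.76, adjusted p = 0.0491), the transferrin receptor TFRC (-0.76), PNN (-0.66) and 1 unnamed probe set (-1.59) fell, and 1 probe set each of POLG and G6PC3 was no longer listed. LAMTOR2, of the lysosomal Ragulator complex, rose by 0.59. At 2 days the counts were 3 or 4 without replicate 1 or 2 of no induction and 15 without replicate 2 of 2 days, and as deposited 0 rose and 8 fell. At 6 days they were 6 without either array of no induction, 3 without replicate 1 and 28 without replicate 2 of 6 days.

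The shRNA control against the T-REx control asks what differs between 2 lines without a knockdown (2 arrays against 2). In experiment 1 the transcription factor SOX11 fell on 3 probe sets (-1.16, -1.31 and -1.52), the calcium buffer CALB1 by 1.26 and the mitochondrial ND4 on 2 (-1.01 and -0.85). With 1 unnamed probe set that rose by 1.60 this makes 7, with 578 at an unadjusted p below 0.05. In experiment 2, 73 rose and 40 fell (113, 61 and 26 genes). SOX11 (205 in T-REx, adjusted p = 3.04e-13), TMEM47 and the matrix protein SPARC were listed on neither shRNA control array. Falls also took in IFI16 (-2.17, SE 0.30), CALB1 (-2.03, SE 0.22) and PLBD1 (-1.51, SE 0.22, 1 of 2 arrays). GCNA rose by 2.83 (SE 0.26, 1 of 2 T-REx arrays), SH3BGR by 1.73 (SE 0.18), the stress-induced GADD45B by 1.67 (SE 0.22), SERTAD1 by 1.62 and DHRS2 by 1.56. The count of 113 was 70 or 53 without T-REx replicate 1 or 2, and 231 or 62 without shRNA control replicate 1 or 2.

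The comparison of knockdowns asks which genes move in more than 1 of them. RUNX1T1 and ITGA8 moved the same way in the Ago1 and Ago2 comparisons, where 281 probe sets fell in both (100.4 for independent lists), 60 rose in both (46.7) and 138 moved in opposite directions (r = 0.115). Values for independent lists were taken for moves in the same direction only, here and below. Whether opposite moves were more or fewer than in independent lists is therefore not given. SLC7A11 moved in opposite directions with Ago1 and Ago3 (1.19 and -1.35 on a probe set other than that named for Ago1), where 145 probe sets moved the same way (51.3 for independent lists) and 61 were opposite (r = 0.0669). In these 2 pairs the same kinds of control line stand on other arrays, so traits of those lines may add to the match, and no value without knockdown was simulated. TP53I3, ZMAT3 and CDKN1A rose with both Ago2 and 6 days of Dicer induction, where 115 probe sets rose in both (38 for independent lists), 137 fell in both (63.9) and 103 were opposite (r = 0.129). Ago1 and Dicer at 6 days had 224 opposite, 46 that rose in both (50.9) and 79 that fell in both (76.6; r = -0.143). Ago3 and Dicer at 6 days had 66 that rose in both (21.8), 34 that fell in both (15.6) and 35 opposite (r = 0.146). ALOX5 and ATP6V0E2 lie among the Dicer genes of 2 and 6 days, where 301 rose in both, 320 fell in both and 0 were opposite (r = 0.691). The same clones and the same vector line stand in both, so fixed line differences alone give such a match, and no value without knockdown was simulated. Ago2 and Ago3 shared their controls: 43 rose in both (20), 41 fell in both (20.4), 56 were opposite, and r was 0.146 against 0.332 in simulated data without any knockdown effect and 0.0583 with the controls split, with a covariance of 0.0189 against 0.0183 simulated. For Ago1 and Ago4, which also shared controls, r was 0.384 against 0.499 simulated and 0.124 with split controls, with a covariance of 0.0313 against 0.0183. The simulation left out the tie between arrays of equal replicate number in experiment 2.

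Lists of known microRNA targets address the most direct expectation, and none passed in any comparison. Of 30 targets of the miR-17 family 6 rose, 3 fell and 21 did not pass at 6 days of Dicer induction (adjusted over the list alone, 8 and 3; median 0.28, adjusted p = 0.143). MICA, a ligand of natural killer cells, rose by 0.83 (SE 0.17), SQSTM1 by 0.55 and ZBTB4 by 0.49. CDKN1A, given above beside the p53 targets, is on this miR-17 list, and TP53INP1 is on both lists. A rise of these genes therefore does not tell the lists apart. MAP3K12 fell by 1.07, E2F3 by 0.87 and CCND2 by 0.83 (SE 0.16). With Ago1 lowered the same list had 1 that rose and 7 that fell (median -0.07, adjusted p = 0.376), and with Ago2 3 and 3 (median 0.06, adjusted p = 0.749). Of 23 miR-15/16 targets 3 rose and 3 fell at 6 days (median -0.07, adjusted p = 0.993), RECK by 1.22 and CCNE1 by -0.81, and 4 fell with Ago2, CCND1 by 1.59 (SE 0.23) and VEGFA by 0.86. Of 19 let-7 targets 1 rose and 3 fell at 6 days (median -0.22, adjusted p = 0.202), TGFBR1 by 0.54, CDK6 by -0.70 and IGF2BP3 by -0.50. Of 19 miR-19/92 targets HIPK3 rose by 0.52 and RHOB fell by 0.40 at 6 days (median 0.32, adjusted p = 0.259), and with Ago2 4 rose and 4 fell, FBXW7 by 0.88 and KLF4 by -1.05 (median 0.21, adjusted p = 0.659). Of 6 HOX targets of miR-196 and miR-10, 1 rose at 6 days (median -0.09, adjusted p = 0.993).

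Housekeeping and machinery lists did not pass as lists either. Of 24 small RNA machinery genes 1 rose and 2 fell at 6 days of Dicer induction (median -0.13, adjusted p = 0.184). Of 28 deadenylation and decapping genes 6 rose and 2 fell with Ago1 (median 0.09, adjusted p = 0.199). Of 12 microRNA host transcripts 1 fell at 6 days (median -0.10, adjusted p = 0.659). Of 31 cytosolic ribosomal protein genes 4 rose and 0 fell with Ago3 (median -0.01, adjusted p = 0.993). Of 40 oxidative phosphorylation genes 1 rose and 6 fell with Ago2 (median -0.05, adjusted p = 0.201). Of 27 proteasome genes 0 rose and 0 fell at 6 days (median -0.07, adjusted p = 0.284). The lowest adjusted p was 0.0574 for 7 kidney genes (Ago4, median -0.18, 0 passing), 0.194 for 5 fibroblast and mesenchymal genes (6-day response, median 0.15, 1 rose) and 0.248 for 10 neuronal genes (Ago1, median -0.12, 2 fell). No gene of the blood cell list was among the probe sets that passed the intensity filter. In all 35 of 261 list tests passed with the preset correlation, and 35 with an estimated one. The calls that did not hold with an estimated correlation were the metallothioneins with Ago1 and at 2 days of Dicer induction and the extracellular matrix list with Ago3 and at 2 and 6 days of Dicer induction, and all other calls held. In their place came immediate early (adjusted p = 0.0413), cell cycle (0.0499) and hypoxia genes (0.0497) with Ago2, p53 targets with Ago4 (0.0499) and interferon-stimulated genes at 6 days (0.0483).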

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

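The tests of short-listing arrays and of RNA quality below were chosen only after the results were seen, while the tests of chance, copy number, fixed line differences and early knockdown were written down before.

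Single arrays stood apart from the other 3 arrays of their set of 4 for 3 targeted probe sets, of 70 sets of 4 looked at, about the 1 in 20 that chance gives. An AGO1 probe set had a log2 value of 7.48 on the first array of Ago4 clone 2 against 7.97 to 8.07 on the others. A DICER1 probe set had 7.53 on the first T-REx array of experiment 1 against 8.05 to 8.15, and AGO2 had 8.55 on the first 2-day array of Dicer clone 2-2 against 8.45 on the others.

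Lines of one kind also differed, by counts from the fit of 19 groups without a line block. In that fit the knockdown lines whose target fell on a probe set differed from their controls at 197 (Ago4 clone 1) to 2982 (Ago2), and Ago4 clone 2, whose AGO4 did not fall, at 71. The 2 Ago1 clones differed at 1 probe set (LAMA5, -1.48), the 2 Ago4 clones at 193, and Dicer clones 2-2 and 2b2 at 803 with no induction named, 579 at 2 days and 1274 at 6 days. AGO4 itself differed by -2.09 between Ago4 clones 1 and 2 (adjusted p = 3.90e-05). The same kind of control differed between experiments 2 and 1 at 224 probe sets for T-REx and 1921 for the shRNA line, and the gap between these controls differed between the experiments at 48, and these counts carry the analysis day as well. The counts that follow come from the fit of arm means with the line block, so they are not directly comparable with those above. There the Ago2 line differed from the Ago3 line at 2158 probe sets and the Ago1 clones from the Ago4 clones at 1998. In the same fit of arm means the response to 6 days of Dicer induction differed from that to 2 days at 1 probe set, CKLF.

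The Ago1 calls are unlikely to come from a chance order of single arrays. The real split of the 8 arrays gave 1546 calls when fitted alone, the highest other split gave 2, and 1 of 35 splits, the real one, reached the real count. Splits ignore the tie between equal replicate numbers and the pairing of arrays by line. Most of them cut through lines, so the test cannot exclude a chance difference between the lines. For Ago4 the real split gave 0 calls, which any split reaches (35 of 35), so that test is void and chance may or may not account for the few Ago4 genes. The short listing on replicate 1 arrays, which the Ago4 clones share in part, is not the likely sole cause, since Ago1 still differs from Ago4 at 1998 probe sets. Those arrays listed 19803 and 19718 probe sets in the Ago1 clones and 20690 and 21135 in the Ago4 clones. The shortfall is thus not equal, and this contrast cannot exclude that it adds to the calls. Copy number could account for part: 72.7% of the called genes moved with the mean of their 20 chromosomal neighbours, against at most 56.2% in shuffled orders, which is short of the 80% set for a main cause. The share alone cannot tell, since it was 82.2% for Ago3 and 85.8% for the Dicer clones with no induction named, yet also 68.9% for the response of the Dicer clones to induction and 80.6% for the 6-day response relative to the vector, in which fixed copy number cancels.

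For the genes that differ between the Dicer clones, 67.4% moved with their neighbours, against at most 53.7% in shuffled orders, and copy number may or may not be the cause. Runs of genes with a neighbour mean beyond 0.4, a bound set after the values were seen, held 109 of 1903 called genes there. The mean induction response of the Dicer clones had 0 genes beyond it (largest 0.371) and the 6-day response relative to the vector 25, none of them called, so the bound may not separate the causes.

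The difference of the Dicer clones from the vector with no induction named may come from fixed line differences, from a leaking hairpin, from RNA quality or from induction that the labels leave out, since it is unknown whether these cells were untreated. Without the 2 arrays of high ACTB ratio 268 probe sets passed against 200 with them, so the number of calls does not rest on those arrays. That count also moved widely when single other arrays were left out, so it cannot exclude RNA quality. The ratio of the difference with no induction named to that at 6 days was 0.569 (0.539 to 0.589 leaving out 1 array; medians of 0.30 and 0.53), against 0.445 for DICER1, but it was taken over the 1005 probe sets called at 2 days, where induced genes lower it whatever the first difference is, so that test is void and fixed differences remain possible. A test of early knockdown on held-out arrays gave -1.29 (-1.31 and -1.27), which is void too because the held-out induced responses were themselves negative (-0.38 and -0.28). DICER1 was already lower, so leak or unnamed induction is possible, and the cause was not settled.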

How the results depend on the processing

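Most results kept their sign under other choices, while counts moved with the block, the filter, array weights and single control or knockdown arrays. Each alternative was set before the data were examined except 3 chosen after: cells left missing, without the 4 short-listing replicate 1 arrays, and without the 2 arrays of high ACTB ratio. With 2 arrays per line, dim signal near background and the number of arrays limit precision, and leaving out 1 array that leaves an arm with 1 sample assumes the lone array varies like other groups. The seed-site test was not run, and the cause of most shifts was not tested. Of 2106 values of named genes and list members with 1 array left out 1903 kept their standing, 179 were weaker (no longer passing), 21 stronger and 3 of the other sign. Of 3608 under other choices 3308 kept it, 190 were weaker, 105 stronger and 5 were counted as of the other sign. These values belong to 286 results, of which 71 were weaker without at least 1 of the arrays and 65 under at least 1 other choice. Among the 5, MT1H at 2 days with clone 2b2 alone is 0.00 and so no difference. Of the other sign were NKRF at 2 days (-0.13, both with cells left missing and without the second 2-day vector array, 4.04 without the first), H2AC6 with Ago1 (0.0240, T-REx control alone), ENO2 before induction (0.19, clone 2-2 alone), FN1 at 2 days (-0.16, clone 2b2 alone), MT1H at 2 days (leaving out 1 array -0.0216, without the first 2-day 2-2 array, to 0.581) and GINS4 at 6 days (-0.42, without the first 6-day vector array, and 1.68 without the second).

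For Ago1 (2328) the count was 1109 beyond 1.5-fold, 1188 against T-REx and 1186 against the shRNA control alone, 1215 with clone 1 and 1427 with clone 2, and 1359 without the 4 short-listing arrays; leaving out 1 array gave 1666 to 2883. For Ago2 (1856) it was 2982 without the line block, 5591 within the experiment alone, 6231 with array weights, 1111 beyond 1.5-fold and 947 against the shRNA control, with 809 to 1651 leaving out 1 array. For Ago3 (693) these were 1326, 2959, 3329, 440 and 266, with 388 against T-REx, and 227 to 574. For Ago4 (4) the count was 7 with no filter or a mean filter, 2 as deposited, 1 with an offset of 1 and 0 with 64, 63 without the block, 0 in the experiment alone, with weights, with cells left missing or without the 4 arrays, 10 against T-REx, 50 with clone 1 and 18 with clone 2, and 0 to 15 leaving out 1 array.

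For Dicer before induction (200) the count was 1220 with no filter, 857 without the block, 40 in the experiment alone and 623 with clone 2b2, with 39 to 434 leaving out 1 array. At 2 days (1005) it was 1577, 1988 and 456 in that order, 2540 with weights, 613 beyond 1.5-fold, 565 with clone 2-2 and 1662 with clone 2b2, and 310 to 1078. At 6 days (1655) it was 2612 with no filter, 2836 without the block, 890 in the experiment alone and 995 beyond 1.5-fold, and 556 to 1603. The 2-day response (12) gave 165 with no filter, 42 without the block, 25 with a replicate block, 55 with weights, 55 with clone 2b2 and 73 without the 2 ACTB arrays, and 7 to 30. The 6-day response (155) gave 326 with no filter, 282 without the block, 35 in the experiment alone, 247 with weights and 269 with clone 2b2, and 33 to 319.

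The vector at 2 days (9) gave 243 with no filter, 25 with a mean filter, 20 with an offset of 64, 17 without the block and 153 with weights, and 3 to 15 leaving out 1 array. The vector at 6 days (10) gave 316 with no filter, 34 with a mean filter, 20 as deposited, 47 with an offset of 64, 2 in the experiment alone, 30 with a replicate block and 369 with weights, and 3 to 28. The control lines gave 13 with no filter, 2 with an offset of 1, 18 in the experiment alone and 119 with weights in experiment 1 (7), and 23 in the experiment alone in experiment 2 (113, 53 to 231 leaving out 1 array). A replicate block elsewhere gave 2417 for Ago1, 1901 for Ago2, 1054 for Dicer at 2 days and 1734 at 6 days. The correlation of Ago2 with Ago3 (0.146) was 0.279 against T-REx alone and 0.0583 with split controls, and that of Ago1 with Ago4 (0.384) was 0.124 with weights, 0.107 without the 4 arrays and 0.124 with split controls. Passing gene list tests ran from 31 to 38 leaving out 1 array (35).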

Other observations

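Some of the large differences belong to genes that also differ between lines of one kind. Of 105 probe sets named by the rule 46 (43.8%) also passed between clones of one target or between the 2 controls of one experiment, against 2082 of 15199 tested (13.7%), and this held for 14 of 20 named for Ago3 and 6 of 20 for Ago1. The named genes were chosen for large differences and the tested ones were not, and the 46 include DICER1, lowered to different depths in the 2 clones, so the 2 shares are not of like genes. SOX11 was listed on neither array of Ago4 clone 1 against 499 in clone 2, and on neither shRNA control array of experiment 2 against 205 in T-REx. PUDP was listed on neither array of Ago4 clone 1 against 421 in clone 2, and on neither array of Dicer clone 2b2 before induction against 158 in clone 2-2. IFI16 differed by -3.12 between the Ago4 clones. LRATD2 was at 35, 22.2 and 25.4 in the empty vector groups and 29.0 in the Ago2 line and at 750 to 1407 in all other groups, so the vector and Ago2 lines are those that stand apart for this gene. PLBD1 stood at 212 and 188 in the Ago1 clones, 152 with Ago3 and 160 and 72.8 in the Ago4 clones, and at 29.2, 36.6 and 48.5 in 3 control groups and 8.83 on 1 of 2 arrays of the shRNA control of experiment 2. Against its controls PLBD1 passed as higher with Ago1 (2.62), Ago2 (1.34), Ago3 (1.85), Ago4 (1.78) and at 2 days of Dicer induction (1.38).

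Runs of neighbouring genes moved together in several comparisons of lines. In the Ago3 line 210 of 456 called genes (46.1%) lay where the mean of 20 neighbours passed 0.4, among them DHCR7 (-1.42, neighbours -0.96), CCND1 (-1.12, neighbours -0.76), CTTN, FADD, NUMA1 and PPFIA1. In the Ago1 clones it was 382 of 1377 (27.7%), with KLF9, ZNF883, HSDL2, PTBP3, GNG10, IGFBPL1 and TCAIM, and in the Ago2 line 213 of 1205 (17.7%), with CD99, PUDP, GTPBP6, KRT18, CALB1, ANXA1 and PSMD5. In the Dicer clones against the vector it was 25 of 127 (19.7%) before induction, 76 of 619 (12.3%) at 2 days and 108 of 1039 (10.4%) at 6 days. STS lay in such a run at all 3 times, HES6 and KLHL7 before induction, and NUDT1 (neighbours -0.68) and UHRF1 (neighbours -0.47) at 6 days. The cholesterol and Wnt calls of the Ago3 line rest in part on DHCR7 and CCND1. A gain or loss of a chromosome segment in each line could give this, which these values cannot tell, and genomic DNA of the same lines hybridised to a copy number array would test it.

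Of 31 amino acid and ER stress genes 9 rose with Ago1, 11 fell with Ago3, and 2 rose and 11 fell at 6 days of Dicer induction, with ASNS at -1.03 in the Ago3 line and -1.12 at 6 days of Dicer induction. Medium exhaustion in a confluent well could do this as well as the knockdown, and it was not tested. Culture at matched density with ATF4 protein measured in each line would separate the 2.

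ATP6V0E2 fell with DICER1 in both clones, from 172 and 189 before induction to 38.8 and 48.9 at 2 days, with 370 in the vector line at 2 days. A hairpin that also matches ATP6V0E2 would give this speed, and so could a microRNA-independent role of Dicer. A second hairpin against another part of DICER1, or a Dicer cDNA that the hairpin cannot cut, would decide. Of 1005 probe sets called at 2 days 615 also passed in both clones in the fit of 19 groups without a line block. In that fit clone 2-2 had 1008 calls against the vector and clone 2b2 had 2304. The clones may thus share only part of their changes, while ATP6V0E2 fell in both.

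CGA was low in the Dicer clones before induction (32.9 in clone 2-2) and reached 416 there and 171 in clone 2b2 at 6 days, while the vector stayed at 204. The hormone subunit responds to cyclic AMP and to histone acetylation, and HDAC activity in the 6-day cells could be measured. The histone genes H2BC12 and H2BC5 rose in the same cells, which may reflect more polyadenylated histone RNA in cells that leave the cycle. Of 36 replication genes 9 were lower there than in the vector, yet the list was already lower before induction (median -0.13) and did not pass in the 6-day response (median -0.09, adjusted p = 0.199), nor did CDKN1A (1.20, adjusted p = 0.0614). DNA content by flow cytometry would show whether the cells arrest in G1. The 6-day response counted 35 probe sets when experiment 3 was fitted alone, so a repeat with more arrays of the vector line is the first need.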
